A study of Homo sapiens with 9 samples.

How the data were processed

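RNA was measured in 9 libraries of hCMEC/D3 cells, 3 from untreated control cultures, 3 after 4 h without oxygen and glucose (OGD) and 3 after the same deprivation followed by 16 h in normal medium (OGD/R). Per the labels, deprived cells stood in glucose-free medium under 95% N2 and 5% CO2, and reoxygenated cells under 21% O2 and 5% CO2. Total RNA was made into libraries with a SMARTer mRNA kit. Groups and replicate numbers were taken from the sample titles. Nothing states that replicates of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

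The deposited table held 1 FPKM value (fragments per kilobase of transcript, scaled to mapped fragments) per gene and library, made by the authors. Per the submitters' processing notes the genome build was GRCh38. The aligner, the quantification tool, the gene annotation and whether strand was used are not given in the sources used here. Values summed to between 442696 and 605818 per library, which shows no scaling to a common total. Whole reads could not be recovered from the low values, so the depth per library is unknown and no counting interval or detection floor was computed. All 9 value columns matched a sample, and 0 pairs of libraries held identical values in over 0.5 of the genes.

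The table listed 15570 genes (15533 protein coding, 37 non-coding). All 15570 matched a record in NCBI RefSeq for GRCh38.p14 by NCBI Gene identifier, and coordinates were taken from there. Long nuclear RNAs, of which 9 were listed for a check of RNA quality, and the 13 mitochondrially encoded messages were not analysed here. Some values at exactly 0 can be failed estimates, since 7 genes were at 0 in at least 1 library and above 10 FPKM in another. Such genes are described as listed at 0, with values per library. Genes that overlap another gene on the genome share reads where strand was not used, and their values are uncertain. The overlap is given where such a gene is first described, and in addition TIMP1 overlaps SYN1, ABCB1 overlaps RUNDC3B, LPCAT3 overlaps EMG1 and KRT18 overlaps KRT8. Histone, ferritin, keratin and ribosomal protein genes also have close copies or pseudogenes with which reads may be shared.

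Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested (10818 genes). Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with no further scaling between libraries. All 9 libraries entered 1 fit of 3 groups (lmFit, then eBayes with an intensity trend), so that the groups shared 1 estimate of the spread, with 6 residual and 6.33 prior degrees of freedom. The 3 comparisons were OGD against control, OGD/R against OGD and OGD/R against control, each 2-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, with a threshold of 0.05, and calls with an absolute log2 fold change of at least 1 were counted beside it. Every adjusted p for a gene comes from limma. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

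Lists of genes had been written before the data were examined. They covered HIF targets and hypoxia response, glycolysis and glucose uptake, ATF4 and amino acid starvation response, ER stress, ATF6 and XBP1 arm, heat shock response, NRF2 and oxidative stress response, nuclear encoded respiratory chain, tight junctions, adherens junctions and catenins, endothelial identity, blood-brain barrier transporters, inflammation, NF-kB targets and cytokines, leukocyte adhesion molecules, interferon-stimulated genes, matrix metalloproteinases and inhibitors, basement membrane and glycocalyx, endothelial to mesenchymal transition, angiogenesis, Notch and VEGF signalling, immediate early genes, KLF and shear response, p53 targets, cell cycle, G1/S and replication, cell cycle, G2/M, cholesterol synthesis and SREBP2 targets, fatty acid synthesis and oxidation, ferroptosis and iron handling, apoptosis and pyroptosis, autophagy and lysosome, cytosolic ribosomal proteins, ribosome biogenesis and MYC targets, replication-dependent histones, pericyte and smooth muscle markers, fibroblast markers, astrocyte, neuron, microglia and leukocyte, and epithelial markers, mitochondrial encoded transcripts and nuclear-retained long RNAs. Each of the 33 lists with at least 5 measured members was tested in each comparison with camera of limma, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over all 99 tests together. Camera asks whether a list moved relative to the other genes. As alternatives camera was run with an estimated correlation and fry on the same fit, which asks whether a list's genes moved, on balance, one way.

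Genes to name were set by a rule with 3 parts, also written beforehand. The first took the 6 largest log2 fold changes in each direction and comparison among called genes with a symbol, at least 10 FPKM in the higher group, no pseudogene annotation and replicates that did not overlap between the groups. The second took up to 4 measured members of each list described, called members with the largest fold changes first. The third always gave 16 genes, namely VEGFA, SLC2A1, HIF1A, CLDN5, OCLN, TJP1, CDH5, PECAM1, VWF, ABCB1, ABCG2, MMP2, MMP9, ICAM1, VCAM1 and TIMP1. Some genes taken by the first 2 parts are not reported here.

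Alternatives planned beforehand were a pseudocount of 0.1 or 5, no expression filter, a stricter filter (mean of at least 5 FPKM), median-of-ratios scaling, quantile normalization, a prior without trend or a robust prior, only the 2 groups compared, protein coding genes only, the replicate number as a block, and leaving out each library in turn. After the data were seen, removal of a smooth trend on transcript length from each library (lowess, span 0.3, longest GENCODE v29 transcript, 10804 of 10818 genes or 99.87%) was added, as was median-of-ratios scaling for the list tests. So were tests of 288 KEGG pathway sets of 15 to 300 genes, taken from the deposited annotation. The overlap of calls that share libraries was compared with 100 simulated data sets without effect.

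The procedure was tested on simulated data with known changes in 3 sizes, on the log2 scale of the fit. For OGD against control it recovered 29 of 67 genes changed by 0.5, 65 of 67 changed by 1 and 62 of 62 changed by 2, and called 10 of 10391 unchanged genes, in a fit of 10587 genes. For OGD/R against OGD it recovered 21 of 66, 65 of 67 and 60 of 60 and called 8 of 10396 unchanged genes (10589 in the fit). For OGD/R against control it recovered 31 of 65, 65 of 67 and 59 of 59 and called 9 of 10383 (10574 in the fit). Of simulated lists of 25 genes in OGD against control, 20 of 20 shifted by 0.5 and 0 of 80 unchanged ones were called with the preset correlation. The 20 shifted lists were also called with the estimated correlation. Simulated genes varied independently of each other, so neither result tests the choice of inter-gene correlation.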

Results

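Gene expression was measured in 9 libraries of hCMEC/D3, an immortalised human brain microvascular endothelial cell line used as a culture model of the blood-brain barrier. The groups were control cells (n = 3), cells after 4 h of oxygen and glucose deprivation (OGD, n = 3), and cells returned for 16 h to normal medium and 21% O2 after the same deprivation (OGD/R, n = 3). The study's stated subject is blood-brain barrier injury in cerebral infarction. FPKM values summed to 492138, 454237 and 537878 in control replicates 1 to 3, to between 585947 and 605818 in OGD, and to between 442696 and 449248 in OGD/R. The number of reads per library is unknown, so no counting error can be given. Of 15570 genes listed, 10818 passed the expression filter and were tested.

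The libraries separated by group. Pearson correlations of log2 values ranged from 0.981 to 0.995 within groups and from 0.923 to 0.977 between groups. The first principal component held 70.1% of the variance and placed OGD at 41.6 to 46.2 and OGD/R at -47.1 to -30.2. Control replicates 1 and 2 lay at -14.5 and -9.97 and control replicate 3 at 7.05, on the OGD side of the other controls. The 36 ribosomal protein genes of a fixed list took 8.34% to 10.5% of summed FPKM in control, 13.5% to 14.1% in OGD and 6.52% to 8.29% in OGD/R. Log2 fold changes also followed transcript length. The slope of log2 FPKM on length averaged -2e-04 ± 0.0649 per doubling in control, -0.182 ± 0.0286 in OGD and 0.182 ± 0.0487 in OGD/R (SD, n = 3), relative to the mean of all libraries. In OGD against control the median fold change went from 0.16 in the shortest of 10 equal bins of transcript length to -0.41 in the longest.

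**Figure D1:**
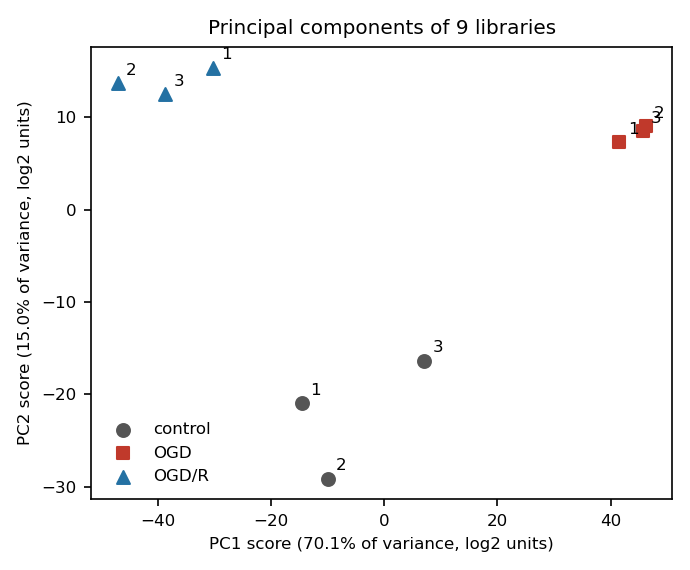
Principal component scores of the 9 libraries (log2 units), with points labelled by replicate number and coloured by group. PC1 runs from OGD/R at -47.1 to OGD at 46.2, and control replicate 3 at 7.05 lies nearer to OGD than the other controls do.

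**Figure D2:**
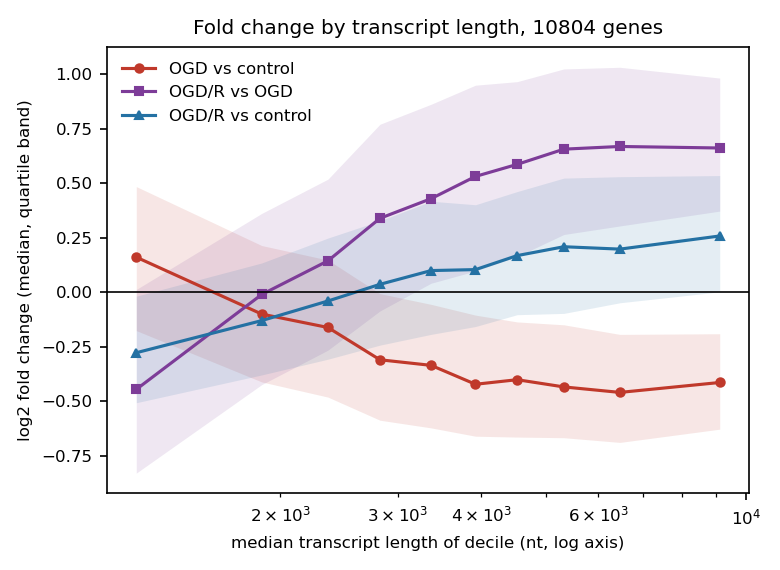
Median log2 fold change of 10804 genes in 10 equal bins of transcript length (log axis, nt), with bands between the quartiles of genes, for the 3 comparisons. OGD against control falls from 0.16 to -0.41 with length, and OGD/R against OGD rises from -0.44 to 0.66.

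The median log2 fold change of all genes also differed from 0, at -0.31 for OGD against control, 0.39 for OGD/R against OGD and 0.07 for OGD/R against control. Medians of gene lists are therefore given after subtracting these values and are called relative medians. Fold changes of single genes are on the deposited scale, and a relative value is given beside some of those within 1 log2 unit of 0. Lists and rules had been fixed before the data were examined. Statements on the largest rises and falls cover called genes with at least 10 FPKM in the higher group and replicates that did not overlap. Where an adjusted p is given for an alternative that ended a call, the alternatives not named kept it. Counts of list members are over all genes tested, and the counts adjusted over the list alone were the same except where given. They cover only members that passed the expression filter. These were 13 of 30 listed for endothelial identity, 12 of 21 for tight junctions and 10 of 26 for angiogenesis, Notch and VEGF signalling. None of the 99 camera tests kept an adjusted p under 0.05 with an estimated inter-gene correlation (0 called, 9 at an unadjusted p under 0.05), against 49 with the preset correlation and 78 by fry.

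The first comparison asked what differed after 4 h of deprivation. Control density, handling and medium changes are not described and cannot be told apart from it. Of the ER stress list, genes of the unfolded protein response, 19 of 22 measured members were higher in OGD and 0 lower. HSPA5, the ER chaperone BiP, rose from 70.7 ± 4.70 to 691 ± 48.3 FPKM (SD, n = 3, log2 fold change 3.27, SE 0.09, adjusted p = 6.26e-10). DDIT3, which encodes the transcription factor CHOP, rose from 32.0 ± 7.03 to 362 ± 8.60 FPKM (log2 fold change 3.48, SE 0.14, adjusted p = 1.02e-08). TXNIP, a thioredoxin-binding protein whose transcript is induced by glucose, fell from 18.6 ± 1.17 to 1.08 ± 0.144 FPKM (log2 fold change -3.24, SE 0.12, adjusted p = 9.82e-09). Ribosomal protein genes were higher, whereas HIF targets, interferon-stimulated genes and cell cycle genes were lower.

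At an adjusted p under 0.05, 6272 genes differed, 1218 higher and 5054 lower in OGD. Of these, 670 changed at least 2-fold (169 higher, 501 lower), and 1089 did when control replicate 3 was left out. The balance of directions depended on scaling. It was 2863 higher and 2495 lower after median-of-ratios scaling, 2166 and 2427 after quantile normalization, and 2423 and 2317 after the transcript length trend was removed, an alternative chosen after seeing the data. Of the calls on the deposited scale, 3713 kept their direction under median-of-ratios scaling.

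HSPA5 lies on GRCh38 (NCBI Gene 3309, chromosome 9, 125234853 to 125241343), as do DDIT3 (NCBI Gene 1649, chromosome 12, 57516588 to 57520517), which overlaps MARS1 on the genome, and TXNIP (NCBI Gene 10628, chromosome 1, 145992435 to 145996579). The other large rises were those of the ER proteins SDF2L1 (from 32.4 to 211 FPKM, log2 fold change 2.68) and MANF (from 111 to 619 FPKM, 2.51), and of the cytokine gene IL1B (from 26.7 to 138 FPKM, 2.33, NCBI Gene 3553, chromosome 2, 112829751 to 112836779). BEST1, which overlaps the ferritin gene FTH1, read 34.0, 38.3 and 1.91 FPKM in OGD replicates 1 to 3 against 1.13 to 1.64 in control. Its call was lost without OGD replicate 1 (adjusted p = 0.0575) or 2 (adjusted p = 0.0616), with no expression filter (adjusted p = 0.0641) and with a robust prior (adjusted p = 0.0827). The largest falls after TXNIP were those of C1QL1 (from 26.7 to 3.39 FPKM, -2.63), the transcription factor CEBPD (from 85.4 to 16.0 FPKM, -2.35), OGA, which removes O-linked N-acetylglucosamine from proteins (from 20.2 to 4.03 FPKM, -2.07), and PLEKHA2 (from 13.9 to 2.78 FPKM, -1.89). UHMK1 fell by 1.90 on the log2 scale. That call was lost after median-of-ratios scaling, quantile normalization or length trend removal, with no expression filter and with a robust prior (adjusted p from 0.0734 to 0.0995).

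**Figure D3:**
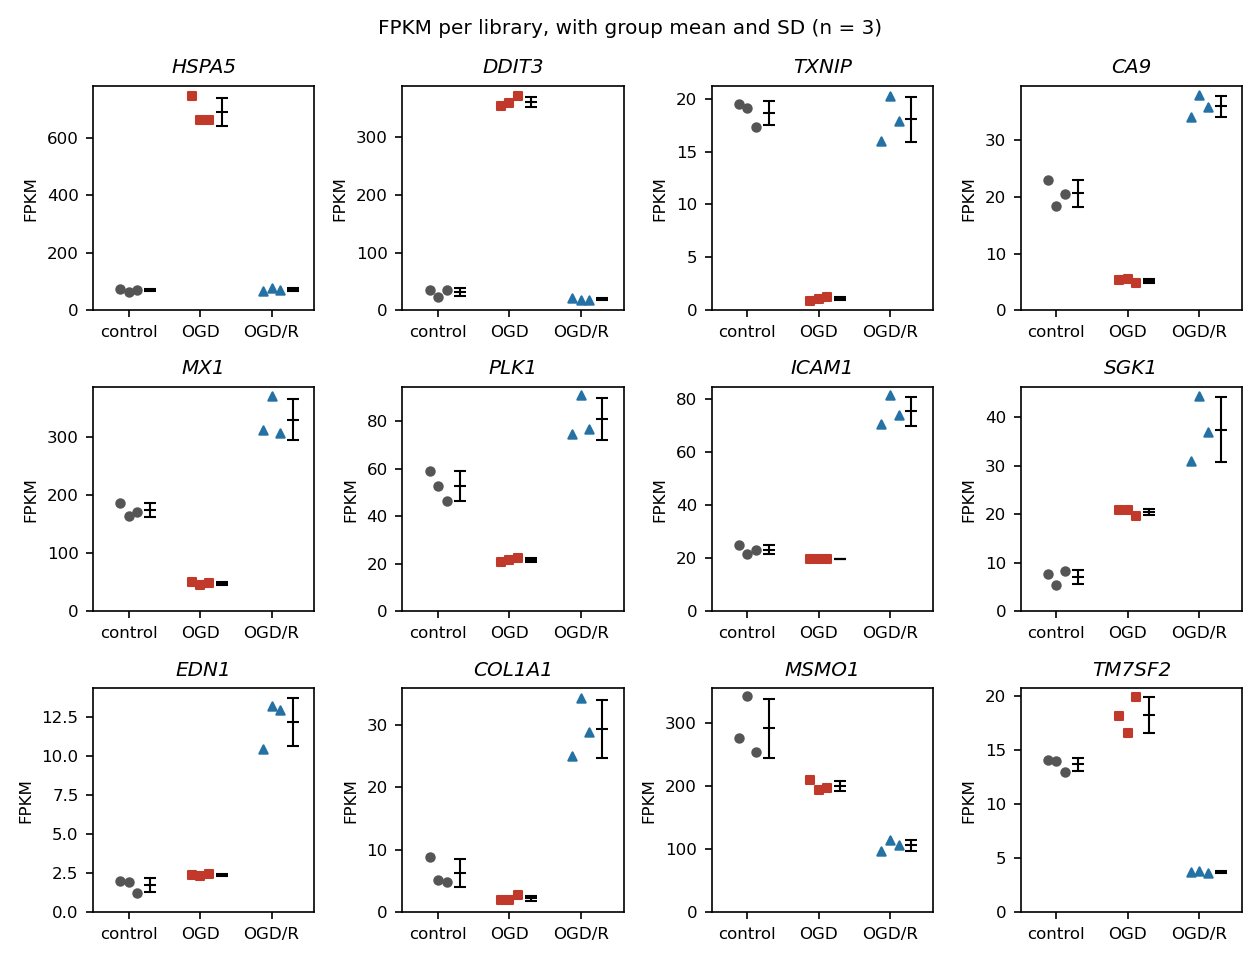
FPKM of 12 genes in each library (linear axis from 0) for control, OGD and OGD/R, with the group mean and SD beside the points (n = 3). HSPA5 and DDIT3 are highest in OGD (means 691 and 362), TXNIP, CA9, MX1 and PLK1 are lowest there, and ICAM1, SGK1, EDN1 and COL1A1 are highest in OGD/R.

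In the ER stress list the test gave relative median 1.56, adjusted p = 1.24e-23, and adjusted p = 0.394 with an estimated correlation. CRELD2 rose from 19.7 to 80.4 FPKM (log2 fold change 2.02) beside HSPA5, SDF2L1 and MANF. Of the ATF4 and amino acid starvation list, 20 of 26 members were higher and 2 lower, or 21 higher and 2 lower adjusted over the list alone, with relative median 0.92, adjusted p = 8.43e-17, and adjusted p = 0.394 with an estimated correlation. Its members NUPR1 (1.54), STC2 (1.59) and PPP1R15A, a regulatory subunit of the eIF2-alpha phosphatase (1.31), rose with DDIT3. The NRF2 list had 7 higher and 6 lower of 20 (relative median 0.29, adjusted p = 0.0109, and adjusted p = 0.394 with an estimated correlation), while its median on the deposited scale was -0.02. FTL, the ferritin light chain, rose from 1649.8 to 3430.5 FPKM, though not after quantile normalization (adjusted p = 0.0624). TXN, thioredoxin, rose from 761 to 1456 FPKM, and GCLM, a subunit of a glutathione-synthesising enzyme, fell from 8.54 to 4.32 FPKM. The list's call was lost after quantile normalization (adjusted p = 0.461) and length trend removal (adjusted p = 0.0526). The ferroptosis and iron list had 6 higher and 5 lower of 16, or 7 higher and 6 lower adjusted over the list alone, with relative median 0.53, adjusted p = 0.00348, and adjusted p = 0.394 with an estimated correlation, and was lost after quantile normalization (adjusted p = 0.0675). Length trend removal brought it to a median 0.31, adjusted p = 0.0102. STEAP3, a ferrireductase, rose from 2.27 to 7.48 FPKM and the lysophospholipid acyltransferase LPCAT3 fell from 5.17 to 1.502 FPKM. The heat shock list was not called (3 higher and 9 lower of 17, or 3 higher and 10 lower adjusted over the list alone, adjusted p = 0.921), and HSPA1A fell from 16.3 to 6.98 FPKM.

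HIF targets were lower in OGD, with 19 of 28 members lower and 1 higher (relative median -0.40, adjusted p = 0.0126, and adjusted p = 0.680 with an estimated correlation). CA9, carbonic anhydrase IX, fell from 20.7 ± 2.35 to 5.22 ± 0.371 FPKM (SD, n = 3, log2 fold change -1.80, SE 0.11, adjusted p = 4.39e-07). DDIT4, an inhibitor of mTORC1 signalling, fell from 241 to 101 FPKM and the transcription factor gene BHLHE40 from 28.8 to 11.3 FPKM. STC2, which is also an ATF4 target, was the member that rose (from 30.6 to 94.2 FPKM). The glycolysis list had 16 of 20 lower and 2 higher (relative median -0.27, adjusted p = 0.0289, and adjusted p = 0.547 with an estimated correlation), a call lost after median-of-ratios scaling (adjusted p = 0.192). LDHA, lactate dehydrogenase A, fell from 1560.3 to 897 FPKM (log2 fold change -0.79, relative value -0.48) and the aldolase gene ALDOC from 54.1 to 20.7 FPKM. Genes of the nuclear encoded respiratory chain had 11 higher and 4 lower of 32, or 8 higher and 4 lower adjusted over the list alone, with relative median 0.46, adjusted p = 2.43e-05, and adjusted p = 0.544 with an estimated correlation. That call was lost after quantile normalization (adjusted p = 0.206) and by fry (adjusted p = 0.249). The list gave median 0.19, adjusted p = 0.0436 with the length trend removed. NDUFA4 rose from 110.3 to 191 FPKM and SDHA, a subunit of complex II, fell from 46.8 to 25.96 FPKM.

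Of 36 ribosomal protein genes 35 were higher and 0 lower (relative median 1.16, adjusted p = 1.00e-25, and adjusted p = 0.394 with an estimated correlation). With the length trend removed the list gave median 0.88, adjusted p = 1.48e-13. RPL37 rose from 221 to 711 FPKM and RPS23 from 507 to 1272 FPKM. Ribosome biogenesis and MYC targets were higher in 17 of 25 (relative median 0.68, adjusted p = 7.38e-12, and adjusted p = 0.394 with an estimated correlation), among them the nucleolar protein gene NPM1 (from 1023 to 1962 FPKM) and ODC1, which makes putrescine (from 42.4 to 90.6 FPKM). All 30 G2/M genes were lower on the deposited scale (relative median -0.55, adjusted p = 8.00e-10, and adjusted p = 0.394 with an estimated correlation), including the kinase gene PLK1 (from 52.6 to 21.6 FPKM, NCBI Gene 5347, chromosome 16, 23678889 to 23690367), which overlaps ERN2, and the mitotic motor gene KIF11 (from 25.7 to 8.87 FPKM). Of the G1/S and replication list, 27 of 30 were lower (relative median -0.28, adjusted p = 0.000137, and adjusted p = 0.547 with an estimated correlation), such as RRM2, a ribonucleotide reductase subunit (from 176 to 80.5 FPKM), and MCM4 of the replicative helicase (from 65.6 to 31.1 FPKM). The fatty acid list had 14 of 17 lower, or 0 higher and 15 lower adjusted over the list alone, with relative median -0.29, adjusted p = 0.00533, and adjusted p = 0.547 with an estimated correlation, and the elongase gene ELOVL6 fell from 17.4 to 6.66 FPKM.

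Interferon-stimulated genes were lower in 21 of 24 and higher in 0 (relative median -0.78, adjusted p = 8.34e-08, and adjusted p = 0.394 with an estimated correlation). MX1, an antiviral GTPase (NCBI Gene 4599, chromosome 21, 41420558 to 41459214), fell from 174 ± 11.96 to 48.2 ± 2.17 FPKM (SD, n = 3, log2 fold change -1.83, SE 0.09, adjusted p = 1.13e-07), and the oligoadenylate synthetase genes OAS2 and OAS3 fell from 62.6 to 22.0 FPKM and from 31.4 to 10.4 FPKM. Immediate early genes had 20 lower and 3 higher of 25 (relative median -0.36, adjusted p = 0.0461, and adjusted p = 0.778 with an estimated correlation). This call was lost without control replicate 3 (adjusted p = 0.0688), without OGD/R replicate 2 (adjusted p = 0.0595) and with no expression filter (adjusted p = 0.0618). EGR1 fell from 31.3 to 8.83 FPKM, KLF10 from 14.2 to 3.90 FPKM and JUNB, which overlaps HOOK2, from 92.3 to 24.1 FPKM, while the kinase gene SGK1 rose from 7.12 to 20.4 FPKM. The NF-kB and cytokine list was not called (6 higher and 8 lower of 24, adjusted p = 0.154). IL1A rose from 1.75 to 6.52 FPKM in it and TNFAIP2 fell from 8.49 to 2.47 FPKM.

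At the junctions, the adherens list had 11 lower and 0 higher of 15, or 1 higher and 12 lower adjusted over the list alone, with relative median -0.32, adjusted p = 0.0402, and adjusted p = 0.547 with an estimated correlation, and lost its call without control replicate 3 (adjusted p = 0.0987). JUP, plakoglobin, fell from 27.8 to 6.67 FPKM and NECTIN2 from 21.6 to 10.2 FPKM. The tight junction list was not called (1 higher and 4 lower of 12, adjusted p = 0.725). TJP1, which encodes the scaffold ZO-1, fell from 10.6 ± 1.08 to 5.33 ± 0.632 FPKM (log2 fold change -0.87, SE 0.12, adjusted p = 0.000164, relative value -0.56), and CLDN1, which overlaps CLDN16, rose from 3.54 to 8.19 FPKM. The endothelial identity list was not called (0 higher and 6 lower of 13, adjusted p = 0.778). CDH5, VE-cadherin, fell from 1.26 to 0.343 FPKM (relative value -0.43, adjusted p = 0.00179, or adjusted p = 0.0507 with the length trend removed). PECAM1 fell from 1.11 to 0.435 FPKM (relative value -0.24, adjusted p = 0.00580). That call was lost after quantile normalization (adjusted p = 0.106) and length trend removal (adjusted p = 0.599). CLDN5, VWF, MMP9 and VCAM1 stayed below the expression filter, at no more than 0.101, 0.0881, 0.0594 and 0.903 FPKM in any library. CDH5 and PECAM1 lay near the filter of 1 FPKM, so their changes rest on low values. The blood-brain barrier transporter list was not called (3 higher and 9 lower of 24, adjusted p = 0.699). SLC2A1, the glucose transporter GLUT1, rose from 43.2 to 52.5 FPKM (log2 fold change 0.28, relative value 0.59, adjusted p = 0.0163), a call lost without OGD replicate 1 (adjusted p = 0.0665).

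Of the other fixed genes, HIF1A fell from 78.8 to 49.7 FPKM (relative value -0.34) and MMP2, gelatinase A, from 16.0 to 9.15 FPKM (relative value -0.42). Means for VEGFA (36.6 in control, 31.5 in OGD), OCLN (3.35, 3.28), ABCB1 (0.951, 0.661) and ABCG2 (1.18, 0.823) FPKM did not pass the test. Nor did ICAM1 (23.3, 19.9) and TIMP1 (126, 112). The adjusted p of these 6 genes ran from 0.0572 to 0.922, and with the length trend removed OCLN was higher in OGD (0.42, adjusted p = 0.0294) and TIMP1 lower (-0.37, adjusted p = 0.0119). Without control replicate 3, VEGFA (adjusted p = 0.0172), ABCB1 (adjusted p = 0.0441) and ABCG2 (adjusted p = 0.0488) were called lower. ICAM1 was called lower with no expression filter and without control replicate 2 or OGD/R replicate 2 (adjusted p from 0.0332 to 0.0451). Leukocyte adhesion molecules (0 higher and 4 lower of 8, adjusted p = 0.420), metalloproteinases and inhibitors (3 higher and 6 lower of 18, adjusted p = 0.337) and basement membrane and glycocalyx genes (3 higher and 10 lower of 22, adjusted p = 0.955) were not called as lists. Neither were endothelial to mesenchymal transition (5 higher and 11 lower of 22, or 5 higher and 12 lower adjusted over the list alone, adjusted p = 0.575) and angiogenesis, Notch and VEGF signalling (2 higher and 5 lower of 10, adjusted p = 0.623). The KLF and shear response list (2 higher and 4 lower of 7, or 3 higher and 4 lower adjusted over the list alone, adjusted p = 0.703) had a median of -0.50 and a relative median of -0.19 while its test pointed higher. The relative median and the test also differed in sign, with no call, for tight junctions (-0.01), endothelial identity (0.07) and endothelial to mesenchymal transition (-0.01). So they did for cholesterol synthesis (0.07), histones (0.09) and pericyte markers (-0.01). SNAI2 rose from 6.32 to 17.6 FPKM and TAGLN, which overlaps PCSK7, from 53.6 to 174 FPKM. The lists of p53 targets (5 higher and 8 lower of 23, adjusted p = 0.398), cholesterol synthesis and SREBP2 targets (3 higher and 11 lower of 24, or 3 higher and 12 lower adjusted over the list alone, adjusted p = 0.637) and apoptosis and pyroptosis (1 higher and 13 lower of 23, adjusted p = 0.577) were not called. Autophagy and lysosome genes were not called either (4 higher and 15 lower of 25, adjusted p = 0.451). Replication-dependent histones were not called (0 higher and 3 lower of 13, or 0 higher and 2 lower adjusted over the list alone, adjusted p = 0.921), but were called lower with the length trend removed (median -0.75, adjusted p = 0.00505). Markers of pericytes (2 higher and 5 lower of 9, adjusted p = 0.577) and fibroblasts (1 higher and 6 lower of 8, adjusted p = 0.465) were not called, and POSTN in the latter rose from 22.5 to 82.5 FPKM.

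The second comparison asked how deprived cells differed after 16 h of reoxygenation in normal medium. Oxygen, glucose, medium and 16 h more of culture changed together, so no difference can be assigned to 1 of them. The ER stress and ATF4 genes fell, and HIF targets, glycolysis, interferon-stimulated, immediate early and adherens junction genes rose. DDIT3 fell from 362 ± 8.60 to 19.3 ± 1.60 FPKM (SD, n = 3, log2 fold change -4.16, SE 0.14, adjusted p = 1.94e-09) and HSPA5 from 691 ± 48.3 to 72.2 ± 4.34 FPKM (log2 fold change -3.24, SE 0.09, adjusted p = 6.99e-10). TXNIP rose from 1.08 ± 0.144 to 18.0 ± 2.11 FPKM (log2 fold change 3.19, SE 0.12, adjusted p = 5.05e-09), and COL1A1, a chain of type I collagen, from 2.24 ± 0.450 to 29.3 ± 4.65 FPKM (log2 fold change 3.22, SE 0.19, adjusted p = 1.20e-07). Ribosomal protein genes fell.

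The test called 7648 genes, 5770 higher and 1878 lower in OGD/R, and 2221 of them changed at least 2-fold (1840 higher, 381 lower). After median-of-ratios scaling 3525 were higher and 3704 lower, after quantile normalization 3399 and 3386, and after length trend removal 3267 and 3222. Median-of-ratios scaling kept the direction of 5403 calls.

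The largest rises besides TXNIP and COL1A1 were those of NLGN2 (from 0.952 to 16.2 FPKM, log2 fold change 3.19), the splicing factor gene SRRM2 (from 3.22 to 33.1 FPKM, 3.01), EGR1 (from 8.83 to 76.4 FPKM, 2.98) and CLSTN1, which overlaps PIK3CD (from 3.41 to 32.8 FPKM, 2.94). Besides DDIT3 and HSPA5, the largest falls were those of SDF2L1 (from 211 to 19.0 FPKM, -3.40), MANF (from 619 to 69.4 FPKM, -3.14) and the signal peptidase gene SEC11C (from 159.9 to 28.5 FPKM, -2.45). SYS1-DBNDD2, a readthrough of overlapping genes, read 7.66 to 14.0 FPKM in OGD and 4.94, listed at 0 and listed at 0 in OGD/R, with the call lost without OGD/R replicate 2 (adjusted p = 0.0512) and with a robust prior (adjusted p = 0.0636).

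Of the ER stress list, 16 of 22 were lower and 3 higher (relative median -1.25, adjusted p = 1.42e-10, and adjusted p = 0.394 with an estimated correlation), with DNAJB9 falling from 54.0 to 11.03 FPKM. The ATF4 list had 20 lower and 3 higher of 26 (relative median -1.25, adjusted p = 1.04e-10, and adjusted p = 0.394 with an estimated correlation), and ASNS, asparagine synthetase, fell from 118 to 24.96 FPKM. HIF targets rose in 20 of 28 and fell in 1 (relative median 0.57, adjusted p = 0.00533, and adjusted p = 0.623 with an estimated correlation). CA9 (NCBI Gene 768, chromosome 9, 35673928 to 35681159) rose from 5.22 ± 0.371 to 36.0 ± 1.88 FPKM, ANGPTL4 from 1.29 to 9.51 FPKM and LOXL2, a lysyl oxidase, from 33.3 to 109 FPKM. The glycolysis list rose in 18 of 20 (relative median 0.51, adjusted p = 0.000468, and adjusted p = 0.394 with an estimated correlation), including the hexokinase gene HK1 (from 12.3 to 41.7 FPKM) and the pyruvate kinase gene PKM (from 450.1 to 1089 FPKM). Respiratory chain genes had 21 lower and 3 higher of 32 (relative median -0.92, adjusted p = 4.39e-08, and adjusted p = 0.394 with an estimated correlation), with COX7A2 going from 1056 to 439 FPKM. Length trend removal brought the list to a median -0.34, adjusted p = 0.00908. All 36 ribosomal protein genes fell (relative median -1.76, adjusted p = 1.44e-23, and adjusted p = 0.394 with an estimated correlation). With the length trend removed they gave median -1.32, adjusted p = 2.09e-12. RPS14 fell from 1303 to 403 FPKM.

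Interferon-stimulated genes were higher in 21 of 24, or 22 higher and 0 lower adjusted over the list alone, with relative median 1.05, adjusted p = 5.55e-06, and adjusted p = 0.394 with an estimated correlation, and MX1 rose from 48.2 ± 2.17 to 329 ± 34.7 FPKM. Of the immediate early genes 24 of 25 rose (relative median 0.80, adjusted p = 2.08e-05, and adjusted p = 0.547 with an estimated correlation), NR4A1 from 0.949 to 13.6 FPKM among them. The NF-kB and cytokine list had 19 higher and 2 lower of 24 (relative median 0.63, adjusted p = 0.00701, and adjusted p = 0.574 with an estimated correlation), and median 1.05, adjusted p = 4.45e-06 with the length trend removed. ICAM1, a leukocyte adhesion molecule (NCBI Gene 3383, chromosome 19, 10271120 to 10286615), rose from 19.9 ± 0.0363 to 75.3 ± 5.60 FPKM (log2 fold change 1.87, SE 0.09, adjusted p = 3.58e-08), and NFKBIZ, which overlaps NXPE3, from 2.23 to 15.8 FPKM. G2/M genes rose in 28 of 30 and fell in 1 (relative median 0.46, adjusted p = 4.87e-05, and adjusted p = 0.547 with an estimated correlation), with MKI67, the Ki-67 gene, going from 1.48 to 11.2 FPKM. Of the cholesterol list 12 of 24 fell and 4 rose (relative median -0.67, adjusted p = 2.43e-05, and adjusted p = 0.394 with an estimated correlation). MVD of the mevalonate pathway fell from 87.1 to 33.1 FPKM.

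The adherens list rose in 14 of 15 (relative median 0.75, adjusted p = 0.00503, and adjusted p = 0.394 with an estimated correlation), with JUP going from 6.67 to 35.1 FPKM and NECTIN2 from 10.2 to 43.5 FPKM. The basement membrane and glycocalyx list had 18 higher and 1 lower of 22 (relative median 0.68, adjusted p = 0.00879, and adjusted p = 0.623 with an estimated correlation). AGRN, agrin, rose from 3.82 to 29.3 FPKM and COL4A2, a type IV collagen chain, from 9.11 to 40.3 FPKM. The NRF2 list had 7 higher and 7 lower of 20 (relative median -0.31, adjusted p = 0.0318, and adjusted p = 0.394 with an estimated correlation) and a median of 0.08 on the deposited scale. This call was lost after quantile normalization (adjusted p = 0.825), length trend removal (adjusted p = 0.2003) and without control replicate 2 (adjusted p = 0.0543). The ferroptosis and iron list had 4 higher and 9 lower of 16 (relative median -0.78, adjusted p = 0.00533, and adjusted p = 0.394 with an estimated correlation), lost after quantile normalization (adjusted p = 0.162), and FTL fell from 3430.5 to 1011 FPKM. Length trend removal brought this list to a median -0.43, adjusted p = 0.0173.

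TJP1 rose from 5.33 ± 0.632 to 16.4 ± 1.63 FPKM (relative value 1.07, adjusted p = 1.12e-06) in a tight junction list that was not called (8 higher and 0 lower of 12, adjusted p = 0.393). VEGFA rose from 31.5 to 73.1 FPKM (relative value 0.79), SLC2A1 from 52.5 to 98.7 FPKM (relative value 0.51), MMP2 from 9.15 to 31.3 FPKM (relative value 1.27) and CDH5 from 0.343 to 1.97 FPKM (relative value 0.74). Of the 16 fixed genes, 4 called higher turned direction with scaling or length trend removal. PECAM1 (from 0.435 to 1.27 FPKM) went to -0.03, HIF1A (from 49.7 to 65.2 FPKM) to -0.14 and ABCB1 (from 0.661 to 1.17 FPKM) to -0.22 on the log2 scale with the length trend removed. TIMP1 (from 112 to 152 FPKM) went to -0.03, and HIF1A to -0.08, after median-of-ratios scaling. Calls were lost after quantile normalization for PECAM1 and ABCB1 (adjusted p = 0.191 and 0.660) and without OGD/R replicate 2 for HIF1A (adjusted p = 0.0530). ABCB1 also lost its call after median-of-ratios scaling (adjusted p = 0.281) and without OGD replicate 1 or 3 or OGD/R replicate 2 or 3 (adjusted p from 0.0665 to 0.113). OCLN (3.28 and 3.70 FPKM) and ABCG2 (0.823 and 0.661 FPKM) did not pass the test (adjusted p = 0.450 and 0.453), and OCLN was lower with the length trend removed (-0.54, adjusted p = 0.00543) and after quantile normalization (-0.45, adjusted p = 0.0150). ABCG2 was called lower after median-of-ratios scaling (adjusted p = 0.0472), quantile normalization (adjusted p = 0.00243) and length trend removal (adjusted p = 0.000557).

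Other lists missed the threshold. Among them were blood-brain barrier transporters (16 higher and 1 lower of 24, adjusted p = 0.0624), endothelial identity (10 higher and 0 lower of 13, adjusted p = 0.119) and leukocyte adhesion (7 higher and 0 lower of 8, adjusted p = 0.0983). Metalloproteinases (13 higher and 2 lower of 18, or 14 higher and 2 lower adjusted over the list alone, adjusted p = 0.0860), endothelial to mesenchymal transition (16 higher and 2 lower of 22, or 17 higher and 2 lower adjusted over the list alone, adjusted p = 0.0970) and angiogenesis (8 higher and 1 lower of 10, adjusted p = 0.0540) were not called. Nor were G1/S (23 higher and 1 lower of 30, adjusted p = 0.0754), fatty acids (13 higher and 0 lower of 17, adjusted p = 0.0679) and heat shock (10 higher and 2 lower of 17, adjusted p = 0.649), whose relative medians were 0.06, 0.18 and -0.03, and their medians after median-of-ratios scaling -0.00422, 0.11 and -0.11. The lists of KLF and shear (4 higher and 2 lower of 7, adjusted p = 0.946), p53 targets (9 higher and 2 lower of 23, adjusted p = 0.725) and apoptosis (10 higher and 3 lower of 23, adjusted p = 0.867) were not called. Autophagy (14 higher and 4 lower of 25, adjusted p = 0.623), ribosome biogenesis (11 higher and 8 lower of 25, adjusted p = 0.228) and histones (4 higher and 0 lower of 13, adjusted p = 0.778) were not called. Pericyte (6 higher and 2 lower of 9, adjusted p = 0.584) and fibroblast markers (6 higher and 1 lower of 8, adjusted p = 0.228) were not called. Some of these lists were called higher under alternatives other than fry. Angiogenesis was after median-of-ratios scaling, quantile normalization and length trend removal, with the replicate block, and without OGD or OGD/R replicate 2 or 3 (adjusted p from 0.0187 to 0.0470). Metalloproteinases were after the same 3 adjustments and without any 1 OGD replicate (adjusted p from 0.0187 to 0.0310). Endothelial identity was with the length trend removed (adjusted p = 0.0193). Endothelial to mesenchymal transition (adjusted p from 0.0121 to 0.0298) and G1/S (adjusted p from 0.00816 to 0.0306) were after quantile normalization and length trend removal and with no expression filter. Transporters were with no expression filter and without OGD replicate 3 or control replicate 1 or 2 (adjusted p from 0.0133 to 0.0487). Fatty acids were with no expression filter (adjusted p = 0.0195) and after quantile normalization (adjusted p = 0.0420), leukocyte adhesion with no expression filter (adjusted p = 0.0334), and heat shock after quantile normalization (adjusted p = 0.0159). For heat shock the relative median (-0.03) and the test differed in sign. With the length trend removed the histone list was called higher (median 0.98, adjusted p = 0.00534), the opposite of its camera direction on the deposited scale.

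**Figure D4:**
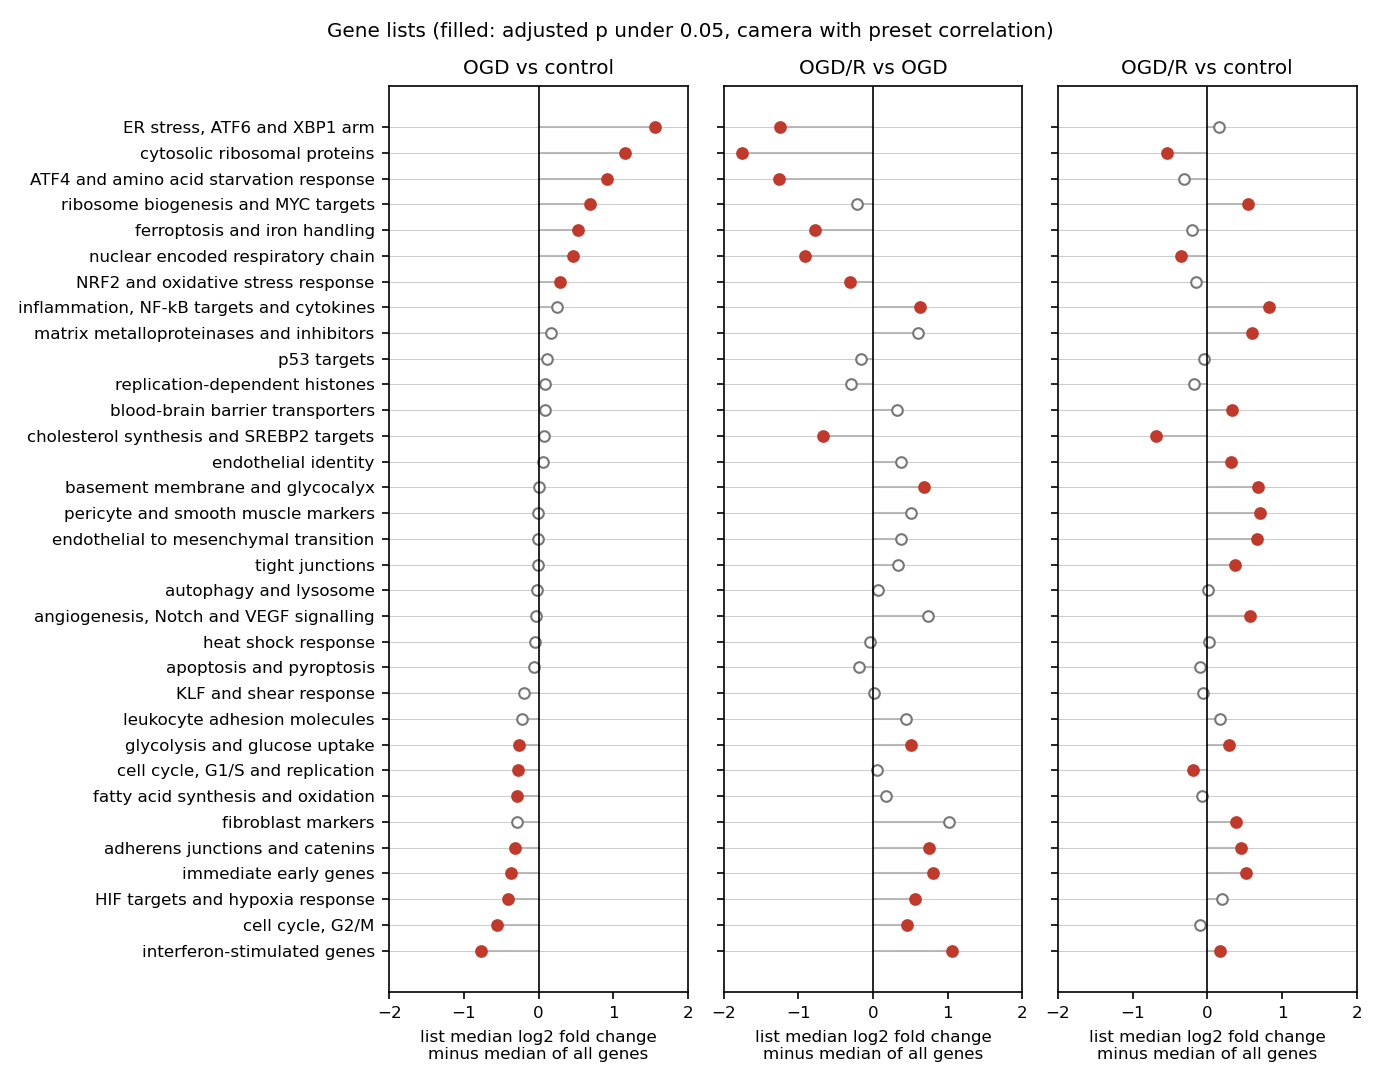
Median log2 fold change of 33 gene lists minus the median of all genes, for the 3 comparisons, with filled points for lists at an adjusted p under 0.05 (camera, preset correlation). The ER stress list lies at 1.56 in OGD against control and -1.25 in OGD/R against OGD, and ribosomal proteins at 1.16 and -1.76.

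The third comparison asked how cells after deprivation and reoxygenation differed from untreated cells. Time and medium changes of controls are not described, so these cannot be told apart from the treatment. Genes of inflammation, matrix, proteolysis and immediate early response were higher in OGD/R, and genes of cholesterol synthesis were lower. EDN1, the vasoconstrictor endothelin 1, rose from 1.74 ± 0.431 to 12.2 ± 1.53 FPKM (SD, n = 3, log2 fold change 2.27, SE 0.15, adjusted p = 2.54e-06). ICAM1 rose from 23.3 ± 1.70 to 75.3 ± 5.60 FPKM (log2 fold change 1.65, SE 0.09, adjusted p = 2.54e-06). MSMO1, a sterol oxidase of cholesterol synthesis, fell from 291 ± 46.3 to 106 ± 8.35 FPKM (log2 fold change -1.44, SE 0.11, adjusted p = 5.85e-06).

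Here 4460 genes were called, 2673 higher and 1787 lower in OGD/R, and 377 changed at least 2-fold (329 higher, 48 lower). The split was 2393 higher and 2493 lower after median-of-ratios scaling, 2394 and 2504 after quantile normalization and 2374 and 2372 after length trend removal. Under median-of-ratios scaling 4159 calls kept their direction.

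EDN1 (NCBI Gene 1906, chromosome 6, 12230516 to 12297194), COL1A1 (NCBI Gene 1277, chromosome 17, 50184101 to 50201631) and MSMO1 (NCBI Gene 6307, chromosome 4, 165327669 to 165343164) lie on GRCh38. SGK1 rose from 7.12 to 37.4 FPKM (log2 fold change 2.25) and COL1A1 from 6.29 to 29.3 FPKM (2.09). ZC3H11A rose from 0.967 to 19.7 FPKM while ZBED6, which lies within it and shares its transcripts, fell from 10.5 to 3.35 FPKM, so that both values are uncertain. CTNND1, which encodes p120 catenin, read 13.2, listed at 0 and 9.69 FPKM in control replicates 1 to 3 and 20.6 to 25.2 FPKM in OGD/R. Its call was lost without any 1 of the OGD/R replicates, with no expression filter, a pseudocount of 0.1, a robust prior or the length trend removed (adjusted p from 0.0586 to 0.129). The largest falls besides MSMO1 included that of TM7SF2, a sterol reductase (from 13.6 to 3.73 FPKM, -1.63, NCBI Gene 7108, chromosome 11, 65111872 to 65116230). Others were those of FABP3, which overlaps ZCCHC17 (from 14.2 to 3.90 FPKM, -1.60), GET1, which overlaps LCA5L and GET1-SH3BGR (from 48.7 to 18.1 FPKM, -1.38), and C7orf25 (from 16.2 to 5.18 FPKM, -1.99). C7orf25 lost its call without control replicate 1, with no expression filter, a pseudocount of 0.1 or a robust prior (adjusted p from 0.0537 to 0.105).

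Of the NF-kB and cytokine list 20 of 24 were higher and 0 lower, or 21 higher and 0 lower adjusted over the list alone, with relative median 0.83, adjusted p = 1.58e-09, and adjusted p = 0.394 with an estimated correlation. IL6 rose from 41.4 to 127 FPKM and LIF from 4.40 to 18.7 FPKM. Metalloproteinases and inhibitors had 13 higher and 1 lower of 18 (relative median 0.60, adjusted p = 0.000106, and adjusted p = 0.394 with an estimated correlation). PLAU, urokinase, rose from 88.4 to 249 FPKM, its receptor gene PLAUR from 33.0 to 83.2 FPKM and MMP2 from 16.0 ± 2.67 to 31.3 ± 4.70 FPKM (adjusted p = 0.000310). Basement membrane and glycocalyx genes were higher in 17 of 22 (relative median 0.68, adjusted p = 1.40e-06, and adjusted p = 0.394 with an estimated correlation), with AGRN going from 8.52 to 29.3 FPKM and COL4A2 from 12.2 to 40.3 FPKM. The endothelial to mesenchymal transition list had 14 higher and 0 lower of 22, or 14 higher and 1 lower adjusted over the list alone, with relative median 0.67, adjusted p = 4.06e-05, and adjusted p = 0.394 with an estimated correlation. Its risen members included COL1A1 and the matricellular gene CCN2 (from 196 to 465 FPKM). Immediate early genes rose in 17 of 25, or 18 higher and 0 lower adjusted over the list alone, with relative median 0.52, adjusted p = 1.10e-05, and adjusted p = 0.544 with an estimated correlation, and MYC went from 27.4 to 80.2 FPKM. Angiogenesis and Notch genes rose in 6 of 10, or 7 higher and 1 lower adjusted over the list alone, with relative median 0.57, adjusted p = 0.0125, and adjusted p = 0.547 with an estimated correlation. VEGFA rose from 36.6 ± 9.32 to 73.1 ± 10.2 FPKM (adjusted p = 0.000471) and the Notch target HES1 from 21.9 to 59.2 FPKM. Interferon-stimulated genes had 10 higher and 2 lower of 24, or 11 higher and 2 lower adjusted over the list alone, with relative median 0.17, adjusted p = 0.0144, and adjusted p = 0.574 with an estimated correlation, lost without control replicate 2 (adjusted p = 0.0543), and median 0.33, adjusted p = 0.00115 with the length trend removed. MX1 rose from 174 to 329 FPKM.

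The adherens list rose in 7 of 15, or 9 higher and 0 lower adjusted over the list alone, with relative median 0.45, adjusted p = 0.00533, and adjusted p = 0.394 with an estimated correlation, and CTNNA1, alpha-catenin, which overlaps LRRTM2, went from 44.4 to 79.6 FPKM. Tight junction genes rose in 6 of 12 (relative median 0.37, adjusted p = 0.0292, and adjusted p = 0.547 with an estimated correlation). That call was lost without control replicate 1 (adjusted p = 0.0596) and with no expression filter (adjusted p = 0.101). TJP1 rose from 10.6 ± 1.08 to 16.4 ± 1.63 FPKM (adjusted p = 0.00273). Of 13 endothelial identity genes passing the filter, of 30 listed, 6 rose (relative median 0.32, adjusted p = 0.0430, and adjusted p = 0.547 with an estimated correlation). The call was lost without control replicate 2 (adjusted p = 0.0806) and after quantile normalization (adjusted p = 0.0789). ENG, endoglin, rose from 13.8 to 33.7 FPKM. Blood-brain barrier transporters had 12 higher and 1 lower of 24, or 14 higher and 2 lower adjusted over the list alone, with relative median 0.33, adjusted p = 0.000512, and adjusted p = 0.547 with an estimated correlation. SLC2A1 rose from 43.2 ± 3.12 to 98.7 ± 5.997 FPKM (adjusted p = 4.83e-06) and SLC7A5, the large neutral amino acid transporter, from 17.1 to 43.3 FPKM. CDH5 (1.26 and 1.97 FPKM), PECAM1 (1.11 and 1.27) and OCLN (3.35 and 3.70) did not pass the test. Nor did ABCB1 (0.951 and 1.17), ABCG2 (1.18 and 0.661) and HIF1A (78.8 and 65.2), with adjusted p of these 6 genes from 0.0542 to 0.577. ABCG2 was called lower after median-of-ratios scaling, quantile normalization and length trend removal, without an intensity trend and without control replicate 3 (adjusted p from 0.00463 to 0.0406). HIF1A was called lower after median-of-ratios scaling and length trend removal and without control replicate 3 (adjusted p from 0.00575 to 0.0356), and CDH5 higher without OGD/R replicate 3 (adjusted p = 0.0341). TIMP1 went from 126 to 152 FPKM (adjusted p = 0.0386), a call lost after median-of-ratios scaling (adjusted p = 0.229), in 4 other settings of the fit and without any 1 of control replicates 1 and 2, OGD replicates 1 to 3 or OGD/R replicates 1 and 2 (adjusted p from 0.0510 to 0.139).

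Of the cholesterol list 16 of 24 were lower and 1 higher (relative median -0.69, adjusted p = 2.94e-09, and adjusted p = 0.394 with an estimated correlation). HMGCS1 fell from 172 to 68.3 FPKM and MVD from 74.0 to 33.1 FPKM. Ribosomal protein genes fell in 21 of 36, or 0 higher and 22 lower adjusted over the list alone, with relative median -0.54, adjusted p = 1.00e-07, and adjusted p = 0.547 with an estimated correlation, and RPL7 went from 1234 to 741 FPKM. With the length trend removed this list gave median -0.35, adjusted p = 0.00121. Ribosome biogenesis and MYC targets rose in 17 of 25 (relative median 0.55, adjusted p = 1.21e-05, and adjusted p = 0.394 with an estimated correlation), with the nucleolin gene NCL going from 79.7 to 195 FPKM. Respiratory chain genes had 16 lower and 1 higher of 32 (relative median -0.35, adjusted p = 9.96e-05, and adjusted p = 0.547 with an estimated correlation), and SDHD fell from 189 to 105 FPKM. Length trend removal brought that list to a median -0.17, adjusted p = 0.0439. Glycolysis genes had 9 higher and 1 lower of 20, or 10 higher and 1 lower adjusted over the list alone, with relative median 0.29, adjusted p = 0.00546, and adjusted p = 0.544 with an estimated correlation, and HK2 rose from 3.14 to 7.998 FPKM. The G1/S list had 3 higher and 6 lower of 30, or 2 higher and 2 lower adjusted over the list alone, with relative median -0.19, adjusted p = 0.0461, and adjusted p = 0.766 with an estimated correlation. That call was lost after length trend removal (adjusted p = 0.0775) and quantile normalization (adjusted p = 0.261) and by fry (adjusted p = 0.185). It was also lost without control replicate 1 or 2 or OGD/R replicate 1 or 3 (adjusted p from 0.0606 to 0.101). PRIM1, a DNA primase subunit, fell from 51.0 to 30.2 FPKM.

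Of the tested marker lists of other cell types both were called higher in OGD/R with the preset correlation. The pericyte and smooth muscle list rose in 6 of 9 (relative median 0.71, adjusted p = 0.00533, and adjusted p = 0.394 with an estimated correlation), with PDGFRB going from 2.75 to 5.85 FPKM, MCAM from 24.5 to 59.9 FPKM and TAGLN from 53.6 to 123 FPKM. The fibroblast list rose in 4 of 8 (relative median 0.38, adjusted p = 0.0297, and adjusted p = 0.547 with an estimated correlation), a call lost without control replicate 2 (adjusted p = 0.0735) and with no expression filter (adjusted p = 0.0814), and COL5A1 went from 2.63 to 11.4 FPKM. The same list gave median 0.58, adjusted p = 0.0253 with the length trend removed. HIF targets (11 higher and 4 lower of 28, or 14 higher and 4 lower adjusted over the list alone, adjusted p = 0.0692), ATF4 (9 higher and 11 lower of 26, adjusted p = 0.123) and ER stress (7 higher and 3 lower of 22, or 8 higher and 3 lower adjusted over the list alone, adjusted p = 0.165) were not called. G2/M (8 higher and 10 lower of 30, or 8 higher and 12 lower adjusted over the list alone, adjusted p = 0.491), heat shock (4 higher and 4 lower of 17, adjusted p = 0.725) and NRF2 (4 higher and 5 lower of 20, adjusted p = 0.256) were not called. Leukocyte adhesion (2 higher and 0 lower of 8, adjusted p = 0.131), KLF and shear (2 higher and 1 lower of 7, or 3 higher and 1 lower adjusted over the list alone, adjusted p = 0.703) and p53 targets (6 higher and 5 lower of 23, adjusted p = 0.921) missed the threshold. So did fatty acids (2 higher and 3 lower of 17, adjusted p = 0.655), ferroptosis and iron (5 higher and 5 lower of 16, adjusted p = 0.488) and apoptosis (4 higher and 6 lower of 23, or 4 higher and 7 lower adjusted over the list alone, adjusted p = 0.228). Autophagy (6 higher and 6 lower of 25, adjusted p = 0.984) and histones (1 higher and 0 lower of 13, adjusted p = 0.623) were not called either. Under alternatives other than fry, HIF targets (adjusted p = 0.0187) and ER stress (adjusted p = 0.0208) were called higher after quantile normalization. With no expression filter leukocyte adhesion was called higher (adjusted p = 0.0320) and ATF4 lower (adjusted p = 0.0326). The relative median and the test differed in sign for KLF and shear (-0.05) and p53 targets (-0.05). Single members of uncalled lists still changed, such as HYOU1 (from 11.9 to 35.1 FPKM) in the ER stress list, CHAC1 (from 11.7 to 4.27 FPKM) in the ATF4 list and CDK1 (from 328 to 157 FPKM) in the G2/M list.

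Of 6272 genes called in OGD against control, 5161 (82.3%) were turned back, that is, called in the opposite direction in OGD/R against OGD. These were 950 of 1218 higher genes, against 211 for independent lists of the same sizes, and 4211 of 5054 lower genes, against 2696. Still called the same way in OGD/R against control were 869 genes, 219 higher against 301 for independent lists and 650 lower against 835. Both conditions held for 196 genes. Simulated data with no effect gave means of 0.24 genes called, 0.02 turned back and 0.02 persisting. The simulation leaves out the effects and the independent lists leave out the shared libraries, so neither gives the overlap due to sharing among genes that changed. In 1831 genes the 2 treated groups were called in opposite directions against control (1697 after median-of-ratios scaling, 1221 with the length trend removed). SGK1 and STC2 were higher in both treated groups, whereas HSPA5 returned to 72.2 ± 4.34 FPKM beside 70.7 ± 4.70 in control (SD, n = 3).

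Across genes, which are not independent replicates, the log2 fold changes of OGD and OGD/R against control had a Pearson r of -0.114 and a Spearman rho of -0.150. Unchanged groups simulated against the same controls gave r of 0.501 (range 0.472 to 0.527) and rho of 0.475. The covariance was -0.0265, against a simulated 0.0116, a difference of -0.0381. Part of any shared signal may come from the shared libraries, since 3 controls cannot be split into sets of at least 2. Without control replicate 3 r was 0.0102, and with the length trend removed it was 0.0087.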

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

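The tests of transcript length in this part were chosen after the result was seen, and the comparisons of OGD/R with OGD were planned. In all 3 comparisons fold change followed length, with long transcripts lower and short ones higher in OGD than in control, and the opposite in OGD/R. A constant factor per library, set by a few genes that take more of the FPKM, predicts no slope, but outside the ribosomal proteins and the 100 most abundant genes the slope was -0.17 per doubling of length (SE 0.0393). Length as the whole cause of the ribosomal protein rise was tested by longest annotated transcript. The 36 genes rose by 0.93 on the log2 scale (SD 0.0603 over OGD libraries) beyond 20 genes each of nearest length, which moved by -0.12. Expressed messages may be shorter, which would inflate this. The list (0.85) also rose beyond the shortest length bin (0.16). Differences in RNA integrity or full-length cDNA yield remain open, since slopes within control spread over 0.684 of the control to OGD distance. A faster loss of long messages in deprived cells was not tested.

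Other results drew attention because both treated groups were called against control in opposite directions, and OGD/R against OGD, which tests the difference, was called as well. Listed here are the gene lists, and the genes named as largest changes or fixed beforehand, out of 1831 genes of this kind. Values are log2 fold changes against control on the deposited scale, or medians of them, and the difference is the same value for OGD/R against OGD. A difference of list medians taken this way is the median over members and need not equal the gap between the other 2 medians. Higher in OGD/R and lower in OGD were the lists of glycolysis (-0.58 in OGD, 0.35 in OGD/R, difference 0.89) and, in the same order, adherens junctions (-0.63, 0.51, 1.14), interferon-stimulated genes (-1.09, 0.24, 1.44) and immediate early genes (-0.67, 0.59, 1.19). Lower in OGD/R and higher in OGD were the nuclear encoded respiratory chain (0.15, -0.28, -0.53) and cytosolic ribosomal proteins (0.85, -0.48, -1.37). The calls of these 6 lists rest on the preset correlation and held with the length trend removed. Those of glycolysis, adherens junctions, immediate early genes and the respiratory chain in OGD, and of interferon-stimulated genes in OGD/R, were lost under alternatives given with each list.

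Among genes, the matrix genes COL1A1 (-1.14 in OGD, 2.09 in OGD/R, difference 3.22) and MMP2 (-0.73 in OGD, 0.93 in OGD/R, difference 1.66) were lower in OGD and higher in OGD/R. So were, in the same order, the junction scaffold gene TJP1 (-0.87, 0.59, 1.46) and the transcription factor gene EGR1 (-1.70, 1.27, 2.98). The same held for CLSTN1 (-1.12, 1.82, 2.94), NLGN2 (-2.29, 0.89, 3.19), OGA (-2.07, 0.36, 2.43) and SRRM2 (-0.96, 2.05, 3.01). Of genes of the unfolded protein response, DDIT3 (3.48 in OGD, -0.68 in OGD/R, difference -4.16), MANF (likewise 2.51, -0.63, -3.14) and SDF2L1 (2.68, -0.73, -3.40) ended below control. So did the signal peptidase gene SEC11C (1.88, -0.57, -2.45), the fatty acid binding protein gene FABP3 (0.77, -1.60, -2.37) and the sterol reductase gene TM7SF2 (0.39, -1.63, -2.02). The ER stress (7 higher and 3 lower of 22) and ATF4 lists (9 higher and 11 lower of 26) were not called there.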

How the results depend on the processing

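Removal of the length trend, and median-of-ratios scaling of the list tests, were chosen after the data were seen, and the other alternatives were planned. Over 443 fold changes of named genes and all alternatives, 8924 results kept their side of the threshold, and where called their direction, 192 lost and 59 gained a call, and 14 turned. Over the lists 1540 were the same, 77 lost and 61 gained a call, and 5 turned. A change of direction counts as turned only where a call was made with or without the alternative, so those between uncalled results are among the same. Leaving out 1 library at a time gave 5142 to 6692 genes called in OGD against control, 6843 to 7894 in OGD/R against OGD, 3318 to 4582 in OGD/R against control, 4158 to 5565 turned back, and 45 to 52 of 99 list tests called. The cause of the changes given here was not tested, and depth is unknown.

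The correlation of the fold changes of OGD and OGD/R, -0.114 as reported, was -0.0584 with a pseudocount of 0.1, -0.183 with the stricter filter, -0.0513 after quantile normalization and 0.0087 with the length trend removed. Without 1 library it ran from -0.158 (without OGD/R replicate 1) to 0.0102 (without control replicate 3). Of 99 list tests, 49 were called as reported, 0 with an estimated correlation and 78 by fry. With the length trend removed 53 were, 46 of them in the same direction. Among lists called by fry the direction turned for KLF and shear in OGD against control (median -0.50), and in OGD/R against OGD for p53 targets (0.23), apoptosis (0.21) and histones (0.0934), where fry compares with no change and camera with other genes. It also differed for lists that neither called. Histones in OGD/R against OGD also turned with the length trend removed (0.98).

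Directions of single genes in OGD/R against OGD turned under scaling. With median-of-ratios scaling the log2 values were -0.33 for GJA1, -0.0822 for HIF1A, -0.37 for KRT7, -0.0285 for TIMP1 and -0.13 for CD68. After quantile normalization they were -0.0700 for ABCB1, -0.0727 for H3C10 and -0.45 for OCLN. With the length trend removed they were -0.22 for ABCB1, -0.28 for GJA1, -0.14 for HIF1A, -0.54 for OCLN and -0.0271 for PECAM1, and 0.42 for OCLN in OGD against control.

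Counts of genes changed at least 2-fold moved by more than 1.5 times. Against 670 in OGD against control they were 1451 and 208 with pseudocounts of 0.1 and 5, 376 after quantile normalization, 424 with the length trend removed and 1089 without control replicate 3. Against 2221 in OGD/R against OGD they were 915 with a pseudocount of 5, 1335 after quantile normalization and 1220 with the length trend removed. Against 377 in OGD/R against control they were 737 and 113 with pseudocounts of 0.1 and 5, and 240 with the length trend removed. With the stricter filter, which tests fewer genes, 3662 genes were higher in OGD/R against OGD (5770 as reported) and 1751 in OGD/R against control (2673 as reported, with 1617 lower against 1787).

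The replicate number as a block gave 5956, 7452 and 4128 genes called in the 3 comparisons. The samples share only a number, since 1 of 9 same-numbered pairs deviated together with a correlation above 0.1 (range -0.2 to 0.148) and 2 of 9 libraries correlated best with their own number. Among lists the block changed the call of angiogenesis in OGD/R against OGD (adjusted p = 0.0470, from 0.0540).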

Other observations

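The KEGG sets, the tests of control replicate 3 for mixed or mislabelled RNA, those of HIF targets and those of splits were chosen after results were seen. Of 288 KEGG pathway sets, camera called 118 in OGD against control, 167 in OGD/R against OGD and 97 in OGD/R against control. With an estimated correlation it called 0 in each (8, 15 and 8 at an unadjusted p under 0.05, lowest adjusted p = 0.847), and with the length trend removed 72, 98 and 51 were called in the same direction. The sets named were among the latter (adjusted p from 6.93e-06 to 0.0185). In OGD the sets for protein export (10 higher and 3 lower of 23, relative median 0.51, adjusted p = 0.000170) and aminoacyl-tRNA biosynthesis (10 higher and 5 lower of 43, relative median 0.43, adjusted p = 0.000205) were higher. So was oxidative phosphorylation (43 higher and 11 lower of 106, relative median 0.58, adjusted p = 5.48e-12), which was lower in OGD/R than in control (4 higher and 50 lower of 106, relative median -0.36, adjusted p = 4.84e-07). Chemokine signalling was lower in OGD (2 higher and 76 lower of 105, relative median -0.27, adjusted p = 0.00107) and higher in OGD/R than in OGD (85 higher and 5 lower of 105, relative median 0.39, adjusted p = 0.00137).

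Cells after OGD/R differed from control in sets of adhesion and matrix, by calls that rest on the preset correlation (adjusted p = 0.847 for each set named with an estimated one) and held with the length trend removed. ECM-receptor interaction (25 higher and 1 lower of 39, relative median 0.74, adjusted p = 7.95e-07) and focal adhesion (65 higher and 8 lower of 131, relative median 0.29, adjusted p = 6.89e-05) were higher. Complement and coagulation genes were higher too (18 higher and 1 lower of 27, relative median 0.54, adjusted p = 0.000962). Among degradative pathways, lysosome (52 higher and 10 lower of 116, relative median 0.24, adjusted p = 0.00286) and glycosaminoglycan degradation (10 higher and 0 lower of 15, relative median 0.56, adjusted p = 0.00395) were higher. The autophagy and lysosome list fixed beforehand was not called there (6 higher and 6 lower of 25, relative median 0.00473, adjusted p = 0.984). Peroxisome genes (3 higher and 23 lower of 63, relative median -0.26, adjusted p = 0.000685), steroid biosynthesis (0 higher and 10 lower of 17, relative median -0.46, adjusted p = 3.39e-05) and terpenoid backbone biosynthesis (1 higher and 10 lower of 20, relative median -0.35, adjusted p = 0.000129) were lower.

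Lists with fewer than 5 measured members were not tested as lists, and their members' values in control, OGD and OGD/R (FPKM ± SD, n = 3) were as follows. Of astrocyte markers, GJA1 read 23.8 ± 1.75, 27.9 ± 1.61 and 30.5 ± 1.80, SOX9 3.79 ± 1.09, 2.07 ± 0.225 and 5.93 ± 0.922 and ALDOC, also a glycolytic gene, 54.1 ± 4.45, 20.7 ± 1.24 and 33.5 ± 3.76. Of neuron markers, TUBB3 read 14.3 ± 2.16, 22.2 ± 0.960 and 18.4 ± 2.35. Of microglia and leukocyte markers, CD14 read 1.03 ± 0.153, 0.725 ± 0.0626 and 2.05 ± 0.429 and CD68 18.3 ± 2.01, 21.1 ± 0.493 and 26.6 ± 0.854. Of epithelial markers, KRT7 read 191 ± 27.7, 257 ± 4.80 and 276 ± 11.5, KRT18 173 ± 15.7, 123 ± 4.51 and 236 ± 10.4, KRT8 10.6 ± 2.25, 11.4 ± 0.242 and 9.93 ± 1.04 and CLDN7 2.18 ± 0.673, 1.20 ± 0.314 and 3.07 ± 1.08.

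Along the log2 change from controls 1 and 2 to OGD, control replicate 3 stood at a share of 0.349 over all genes. RNA from OGD cells mixed into it would have moved all genes alike on the FPKM scale. The 14 ER stress genes at least 2-fold higher in OGD stood at a median share of 0.0313 (quartiles 0.0140 to 0.0538), against 0.24 over 436 genes changed at least 2-fold, and the highest share among HSPA5, DDIT3, SDF2L1 and MANF, 0.0714, also argues against an OGD library under its label. The length trend was not the whole cause (share 0.33 once removed). The deviation of control replicate 3 from its group mean correlated at 0.37 with that of OGD/R replicate 1, the highest across groups. On PC1 OGD/R replicate 1 also lay nearer to OGD (-30.2) than replicates 2 and 3 (-47.1 and -38.6). Controls 1 and 2 had 2540 and 2765 genes listed at 0, control 3 1650 and treated libraries 1410 to 1857. Which controls deviate is open. Cell state, such as density or handling, and RNA or library preparation shared across groups remain open and untested.

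HIF targets were lower in OGD than in control, although the cells stood without oxygen. The scaling of the deposited values did not account for this, with a list median of -0.40 (adjusted p = 0.0140) under median-of-ratios scaling, nor did transcript length, with -0.41 (adjusted p = 0.00505) once its trend was removed. Both calls rest on the preset correlation, and with an estimated one the list was not called on the deposited scale (adjusted p = 0.680). The median of the ER stress genes against control, HSPA5 among them, was 1.02 higher in OGD than in OGD/R. This argues against exchanged OGD and OGD/R labels only if these genes rise more in deprivation than on reoxygenation, which was not tested. Oxygen supply and density of the control cells are not described, and these, like the loss of short-lived messages or reduced transcription without glucose, were not tested. As a hypothesis only, not tested by these data, 4 h without glucose may have limited the hypoxic transcript response. Cells deprived of oxygen for 4 h with glucose, compared with OGD, would test it.

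The 6 libraries of a comparison can be split into 3 against 3 in 10 ways, too few for a share under 0.05. In fits of the 2 groups alone, 1 of 10 splits, the real one, gave 5822 genes in OGD against control, and the highest of the others gave 2. For OGD/R against OGD the real split gave 8194 (1 of 10) and the highest other 0, and for OGD/R against control 3581 (1 of 10) and 2.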
